A study of Mus musculus with 32 samples.

How the data were processed

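RNA of mouse liver was measured on 32 Affymetrix arrays, in 8 groups of 4 that combine sex, genotype and diet. The genotypes were wild type (WT) and PXR-null, called knockout (KO) here. PXR, the pregnane X receptor encoded by Nr1i2, is a nuclear receptor that senses drugs and bile acids. The diets were an ethanol (EtOH) diet and a control diet. The design text gives 5% ethanol or a paired-fed control diet for 8 weeks, and states this for females alone. It gives no ethanol share or duration for males, and the replicates are not said to be separate animals. The p-values therefore measure the spread between samples, whatever their origin.

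The deposited values are log2 intensities that the authors had already normalized, in 1 table of 10964 probes and 32 arrays. The submitters' notes name oligo and limma without versions or roles. The background correction, summarization, normalization method and any removal of probes are not stated, and the raw scans were not used here. Array medians lay between 5.288 and 5.435, single values between 1.246 and 13.61, and the correlation between arrays of a group between 0.9913 and 0.9979. Of the array pairs, 0 were identical. An array has no read depth, so the number of arrays per group limits the precision.

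The probe annotation listed 9106 of the probes, 8474 of them with 1 gene symbol and 632 with several, and 1858 probes had no entry. Symbols were brought up to date by gene identifier for 239 probes. Only probes with 1 symbol entered, and where several shared a symbol (36 genes) the probe with the highest mean stood for the gene, which gave 8426 genes. Of these, 3522 are predicted or unnamed loci. Positions follow the RefSeq annotation of GRCm38.p6. Genes such as Cd36, Scd1, Pparg, Srebf1 and Adh1 are not analysed here.

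The values were fitted as deposited with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 32 arrays, empirical Bayes moderation at default settings and no filter on dim genes. There were 14 contrasts: 4 effects of diet (EtOH minus control), 4 of genotype (KO minus WT), 5 interactions (KO minus WT, and female minus male) and the sex difference in control-fed WT (female minus male). Tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and in the results rose, fell, higher and lower without a further word refer to called genes. Errors of differences are standard errors (SE) from the fit, errors of group means are standard deviations (SD), and n is 4 arrays per group throughout. The SE of a gene rests on 1 residual spread shared by all 8 groups. It can therefore be too wide for groups of small spread and too narrow for groups of large spread.

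There were 30 gene lists, of which 24 had at least 3 measured members and were tested with camera, a test in limma that sets a list against all other genes, at a preset correlation between genes of 0.01 and with adjustment over the lists of a contrast. The lists cover xenobiotic genes (PXR targets), ethanol oxidation, NRF2 targets, lipogenesis, cholesterol synthesis, bile acids, fatty acid oxidation, fatty acid uptake and lipid droplets, cytokines, the acute phase, fibrosis, ER stress, sex-biased liver genes in both directions, the circadian clock, the interferon response, fasting glucose, one-carbon metabolism, and markers of liver zones and of other cell types. Lists of cell cycle, neutrophil, B and plasma cell, exocrine pancreas, white adipose and erythroid genes had fewer measured members and were not tested. Alternatives were camera with a correlation estimated per list, and fry, which asks whether the genes of a list move, on balance, one way. Members past the threshold were also counted with p-values adjusted over the list alone.

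The genes named were chosen by a rule. For each contrast it took the 8 largest rises and 8 largest falls among called genes whose groups of 4 did not overlap, without predicted loci, and up to 4 called members per list with the smallest adjusted p. Where fewer than 5 genes were called, it took the 5 with the smallest p. It also took a fixed set, of which Nr1i2, Nr1i3, Cyp3a11, Cyp2b10, Ppara, Thrsp and Cyp2e1 were measured. Lists, contrasts, their tests, the rule and the first set of alternatives were fixed before the data were examined. Tests of patterns seen in the data were chosen later.

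The alternatives fixed at the start were all probes, the mean of a gene's probes, the dimmest 33.33% of genes by mean left out, arrays centred on their medians, quantile normalization, moderation with a trend and robust estimation, array quality weights, fits on the arrays of a contrast alone, the replicate number as a block, and each array of a contrast left out in turn. Added after the data were seen were a term for a set of 10 arrays with a narrower spread of values, the removal of the 2 arrays of control-fed KO females that belong to it, and list tests without array 1 of the EtOH-fed WT males. For other splits of the arrays, all 35 divisions of the 8 arrays of a contrast into 4 and 4 were fitted, and 100 draws were made for each interaction. The fit was tested on simulated data with known changes in 200 genes: at the size of the male WT diet contrast, 85.1% of changes of 0.5 and 98.5% of changes of 1 on the log2 scale were called, at a false share of 8.29%. For diet by genotype in males the simulation called 65.7% of changes of 0.5 and 98.5% of changes of 1, at a false share of 4.37%, so an interaction of 0.5 can be missed. With no simulated change there were 0 false calls. The simulation drew the genes independently, with 1 spread per gene for all groups. Real groups differ in spread: the SD of Cyp2b9 was 4.01 in control-fed WT males and 0.27 in control-fed KO males. Genes that move together and single odd arrays were not simulated, so these shares need not hold for the real contrasts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.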

Results

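Liver RNA of WT and PXR-null (KO) mice of both sexes, fed a control or an EtOH diet, was measured on 32 arrays, 4 in each of 8 groups, and 8426 genes were compared. Nr1i2, the gene of PXR (gene 18171, probe TC1600001602.mm.1, chromosome 16 from 38248349 to 38294849 in GRCm38.p6), had a mean log2 intensity of 8.58 ± 0.23 (SD, n = 4) in control-fed WT females and 8.88 ± 0.07 in control-fed KO females. In control-fed males the means were 8.40 ± 0.26 in WT and 8.94 ± 0.16 in KO. In the control-fed groups Nr1i2 was thus not lower in KO. Where the probe lies relative to the part of the gene that was removed is not known here, so its level does not check the genotype labels.

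The arrays differed in the spread of their values. In 10 arrays, namely all 8 of KO males and arrays 1 and 2 of control-fed KO females, the SD of all log2 values was 2.367 to 2.435, and in the other 22 it was 2.466 to 2.545. The first principal component, with 29.18% of the variance, parted these 10 from the other 22 without overlap. Genotype in males and this spread therefore go together in every array.

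**Figure D1:**
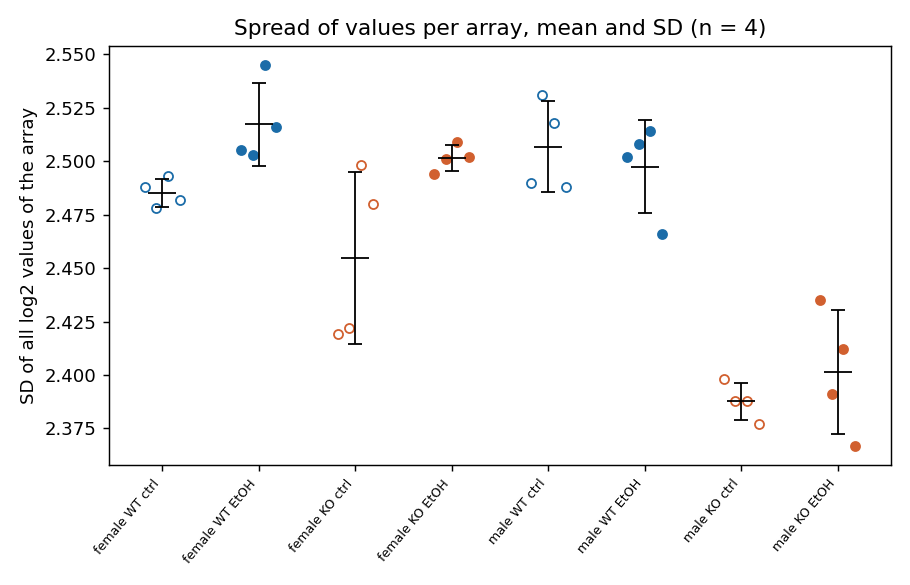
SD of all log2 values of each array, by group; points are arrays (open for control diet, filled for EtOH, blue for WT, orange for KO), and the bars give the group mean and SD (n = 4). The 8 KO male arrays and 2 arrays of control-fed KO females lie at or below 2.435, and all others at or above 2.466.

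Control-fed KO and WT females were compared for what the loss of PXR changes without ethanol. Genes of the Cyp2b cluster, cytochrome P450 enzymes, were far lower in KO. Cyp2b9 (gene 13094, probe TC0700000435.mm.1, chromosome 7 from 26173350 to 26210661) had a mean of 12.65 ± 0.13 (SD, n = 4) in WT and 4.38 ± 0.11 in KO, a log2 difference of -8.27 ± 1.02 (SE, adjusted p = 2.68e-06). Cyp2b13 differed by -7.06 ± 0.68 and Cyp2b23 by -1.25 ± 0.23. The sulfotransferase genes Sult3a2, Sult3a1 and Sult2a7 were higher in KO, by 4.47 ± 0.42, 4.03 ± 0.54 and 3.15 ± 0.41. Cyp2c55, a cytochrome P450 gene, rose from 6.30 ± 0.31 to 8.09 ± 0.19. The low means of Cyp2b9 and Cyp2b13 in KO (4.40 ± 0.13 for Cyp2b13) and of Sult3a2 in WT (3.98 ± 0.47) lie below all array medians (5.288 to 5.435) and near the 4.44 ± 0.21 of Slco1a1, a male-biased gene, in WT females. They are not shown to be above background, so these differences, here and below, do not measure how much transcript was left.

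In the same contrast 234 genes were higher and 236 lower in KO, a balance that centred arrays moved to 400 and 145. Pttg1, which encodes securin, fell by 1.56 ± 0.09, Dhrs9, a retinol dehydrogenase gene, by 1.49 ± 0.21, Camk1d by 1.22 ± 0.28, Nlrp12 by 1.09 ± 0.14 and Rnf170 by 1.06 ± 0.19. Rarres1 and Gucy2c rose by 1.59 ± 0.32 and 1.42 ± 0.22. Of 18 xenobiotic genes, 5 rose, 0 fell and 13 did not pass, and adjusted over the list alone 9 rose and 2 fell. Cyp2c55, Aldh1a1 (0.67 ± 0.14), Cyp3a25 (0.55 ± 0.11) and Ces2a (0.66 ± 0.15) were among the risers. The list was higher by camera (adjusted p = 0.0217), a call lost at adjusted p = 0.611 with an estimated correlation. Cyp3a11, a classic PXR target, differed by 0.16 ± 0.11 and Cyp2b10 by -2.64 ± 0.82, and neither passed (adjusted p = 0.357 and 0.0545).

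Among other lists, 1 of 7 ethanol oxidation genes rose, Aldh1a1, and 4 rose adjusted over the list alone. That list was higher (adjusted p = 0.0472, against adjusted p = 0.391 with an estimated correlation). All 11 Kupffer cell markers had positive differences, with a median of 0.519. Of these Cd5l, a macrophage gene, passed at 1.05 ± 0.23, and 5 passed adjusted over the list alone. The marker list was higher at adjusted p = 0.00398, against adjusted p = 0.611 with an estimated correlation. The 3 cholangiocyte markers were lower (adjusted p = 0.0472, against adjusted p = 0.391 with an estimated correlation), and Sox9 fell by 0.28 ± 0.08. With centred arrays the xenobiotic, ethanol oxidation and cholangiocyte lists no longer passed (adjusted p = 0.0601 for each), and the cholangiocyte list also failed with quantile normalization (0.0721) and with a term for the narrow arrays (0.105). Apoa4, an apolipoprotein gene, rose by 0.80 ± 0.14, Amacr and Cyp27a1 of bile acid synthesis by 0.43 ± 0.09 and 0.44 ± 0.10, and Abcb11, the bile salt export pump, fell by 0.49 ± 0.12.

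The 4 KO arrays lay outside the range of the 4 WT arrays for 1358 genes, 16.1% of those tested, where chance gives 2.86%. Without array 1 or array 2 of the WT females 289 and 294 genes were called, and without the 2 KO arrays of narrow spread 271. Of the 33 called genes named by the rule, 23 passed without each array in turn, and 22 passed with a term for the narrow arrays. Among the 11 that did not pass with it, Cd5l went from 1.05 ± 0.23 to 0.96 ± 0.29, Ces2a from 0.66 ± 0.15 to 0.63 ± 0.18 and Cyp27a1 from 0.44 ± 0.10 to 0.42 ± 0.13. Abcb11 went from -0.49 ± 0.12 to -0.50 ± 0.15 and Sox9 from -0.28 ± 0.08 to -0.19 ± 0.09.

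In EtOH-fed females the same genes of the Cyp2b cluster were lower in KO, and Cyp2b10 passed as well. Cyp2b10 (gene 13088, probe TC0700000430.mm.1, chromosome 7 from 25897658 to 25926624), a target of the receptor CAR, was at 10.36 ± 0.34 (SD, n = 4) in WT and 4.86 ± 0.22 in KO, a difference of -5.50 ± 0.82 (SE, adjusted p = 4.91e-05). On the control diet it differed by -2.64 ± 0.82 without passing, and its diet by genotype term did not pass (adjusted p = 0.563), so the size of the genotype effect is not shown to differ between the diets. Cyp2b9 differed by -8.48 ± 1.02, Cyp2b13 by -7.75 ± 0.68 and Cyp2b23 by -1.93 ± 0.23. Sult3a1 and Sult3a2 were higher in KO by 3.80 ± 0.54 and 3.08 ± 0.42, Cyp2c55 by 2.09 ± 0.31 and the chemokine receptor gene Ccr3 by 1.94 ± 0.31. Hamp, which encodes the iron hormone hepcidin, fell by 1.31 ± 0.25, and Dhrs9, Pttg1 and Rnf170 fell by 1.62 ± 0.21, 1.55 ± 0.09 and 1.51 ± 0.19.

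Genes of the interferon response were higher in EtOH-fed KO than WT females. Of 7 measured, 5 rose and 0 fell, and 6 rose adjusted over the list alone, with a median of 0.859. Igtp rose by 1.62 ± 0.38 and Iigp1 by 1.54 ± 0.43, both GTPases induced by interferon gamma, and Irgm1 and Rtp4 by 0.76 ± 0.23 and 0.73 ± 0.23. The list was higher at adjusted p = 0.000214, against adjusted p = 0.319 with an estimated correlation. Of the Kupffer markers 3 of 11 rose (Cd5l by 0.99 ± 0.23, Adgre1 by 0.83 ± 0.25, Marco by 1.48 ± 0.50), and 8 did adjusted over the list alone. That list was higher at adjusted p = 0.000214, against adjusted p = 0.413 with an estimated correlation. Of 4 T and NK cell markers, Klrk1 (0.36 ± 0.09), Cd8a (0.30 ± 0.10) and Ccl5 (0.54 ± 0.18) rose, and all 4 did adjusted over the list alone. Their list was higher at adjusted p = 0.0048, against adjusted p = 0.319 with an estimated correlation. These markers of other cell types and the interferon genes were thus higher in the same contrast. Whether they moved together from array to array was not examined.

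Metabolic lists also differed between EtOH-fed KO and WT females. Of the xenobiotic genes 8 rose and 2 fell, the same counts as adjusted over the list alone, among them Cyp3a25 (0.56 ± 0.11) and Cyp3a44 (0.95 ± 0.21). This list was higher at adjusted p = 0.0135, lost at adjusted p = 0.427 with an estimated correlation. Of 7 ethanol oxidation genes Aldh1a1 and Aldh1a7 rose (0.56 ± 0.14 and 0.44 ± 0.12), and 3 did adjusted over the list alone. Their list was higher at adjusted p = 0.0135, against adjusted p = 0.295 with an estimated correlation. Of 4 cholesterol synthesis genes 0 passed and 2 rose adjusted over the list alone, with the list higher at adjusted p = 0.0426, against adjusted p = 0.427 with an estimated correlation. Of 5 cytokine and innate signalling genes Tlr4 rose (0.51 ± 0.10), and adjusted over the list alone it was again 1. The list was higher at adjusted p = 0.0212, against adjusted p = 0.319 with an estimated correlation. Of 3 fasting glucose genes Pygl, glycogen phosphorylase, and Fbp1 of gluconeogenesis fell by 0.43 ± 0.10 and 0.25 ± 0.07. Adjusted over the list alone 2 fell, and that list was lower at adjusted p = 0.0426, against adjusted p = 0.319 with an estimated correlation. It also failed with centred arrays (0.0549) and quantile normalization (0.0574). Apoa4 rose by 0.79 ± 0.14, as did the sterol transporter genes Abcg8 and Abcg5, by 0.60 ± 0.17 and 0.50 ± 0.16.

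In this contrast 415 genes were higher and 661 lower in KO, and 1633 genes (19.4%, chance 2.86%) had no overlap between the groups. Without KO arrays 1 or 4 the calls numbered 502 and 708, and without WT arrays 2 or 3 they numbered 687 and 592. Of the 48 called genes named by the rule, 23 passed without each array in turn.

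Control-fed KO and WT males differed in 4684 genes, 2822 higher and 1862 lower, a balance that centred arrays moved to 3685 and 952. Most of these differences were small: 323 of the genes differed at least 1.5 fold, against 119 of the 470 called in control-fed females. Of the 4684 genes, 2340 were not predicted or unnamed loci. Cyp2c55 rose by 2.48 ± 0.31 (SE, n = 4 per group), Ces2a, a carboxylesterase gene, by 1.14 ± 0.15 and Dhtkd1, a mitochondrial dehydrogenase gene, by 1.44 ± 0.11. Sae1 and Igsf23 rose by 1.24 ± 0.08 and 1.32 ± 0.14. Dhrs9 fell by 2.47 ± 0.21 and Pttg1 by 1.57 ± 0.09. Thrsp, a lipogenic regulator, rose from 9.87 ± 1.12 (SD, n = 4) to 11.44 ± 0.29, and the female-typical genes Cyp17a1 and Cyp2a4 by 2.53 ± 0.48 and 2.09 ± 0.38. Cyp3a11 rose by 0.44 ± 0.11, Ppara by 0.49 ± 0.16, Nr1i3, the gene of CAR, by 0.59 ± 0.24, and Nr1i2 by 0.53 ± 0.13.

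The genes of the Cyp2b cluster were compared in control-fed males as well. Cyp2b9 was lower by limma (-3.35 ± 1.02, SE, adjusted p = 0.00953), but the groups overlapped, with WT control arrays 3 and 4 at 4.55 and 4.28 and the KO arrays at 4.18 to 4.83. Without WT control array 1 or 2 the call was lost (-2.28 ± 0.97 and -2.11 ± 0.92, adjusted p = 0.0508 and 0.0612), as it was with a term for the narrow arrays (-3.29 ± 1.80, adjusted p = 0.339). Cyp2b23 (-0.54 ± 0.23) and Cyp2b19 (-0.30 ± 0.12) were lower as well (adjusted p = 0.0448 and 0.0348). Both calls were lost with centred arrays (adjusted p = 0.0851 and 0.112) and without WT control array 2 (adjusted p = 0.266 and 0.273). Cyp2b13 (-1.42 ± 0.68) and Cyp2b10 (-1.41 ± 0.82) did not pass (adjusted p = 0.0752 and 0.14). Cyp2b13 lay at 4.19 and 4.00 in WT arrays 3 and 4, where the KO arrays lay at 4.22 to 4.55.

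Acute phase genes, which encode plasma proteins of inflammation, were lower in control-fed KO males. Of 13 measured 7 fell and 0 rose, the same as adjusted over the list alone. Orm2 fell by 1.86 ± 0.45, Orm1 by 0.74 ± 0.15, Itih3 by 0.56 ± 0.16 and Hpx by 0.37 ± 0.10. The list was lower at adjusted p = 0.00478, against adjusted p = 0.897 with an estimated correlation. Of 10 male-biased liver genes 5 fell, also adjusted over the list alone, among them Mup20 (-1.12 ± 0.22), Gstp1 (-1.33 ± 0.34) and Serpina1e (-0.31 ± 0.07). Their list was lower at adjusted p = 0.0341, against adjusted p = 0.897 with an estimated correlation. Of 11 circadian clock genes 5 rose and 3 fell (Tef 0.70 ± 0.16, Per3 1.06 ± 0.28, Clock -0.75 ± 0.18, Npas2 -0.51 ± 0.13), and adjusted over the list alone 6 rose and 3 fell. That list did not pass (adjusted p = 0.883). Of 3 lipogenesis genes Thrsp rose, and adjusted over the list alone it was again 1 (list adjusted p = 0.461). Of 5 fibrosis genes 3 fell, also adjusted over the list alone, Lum, Pdgfrb and Col4a1, and the list did not pass (adjusted p = 0.106).

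These male counts depend on how the 10 arrays of narrow spread are treated. With quantile normalization 2502 genes were called, with the dimmest 33.33% of genes left out 2583 (898 higher and 1685 lower), and with a term for the narrow set 96, of which 93 were also called without it. With that term the median SE was 1.7 times as large. Only control-fed KO females hold arrays both inside and outside the set (2 and 2). The term was therefore estimated from those arrays and carried over to the males, where it cannot be told apart from genotype. Of the 62 calls of named genes that ended with it, 29 kept a difference at least as large, 6 kept less than 0.5 of it, and the median share kept was 0.985, while the SE grew 1.75 times at the median. Cyp17a1 went from 2.53 ± 0.48 to 2.48 ± 0.85, Cyp2a4 from 2.09 ± 0.38 to 2.10 ± 0.68 and Cyp3a11 from 0.44 ± 0.11 to 0.49 ± 0.19. For Orm2 the difference went from -1.86 ± 0.45 to -1.04 ± 0.77, and for Thrsp from 1.57 ± 0.30 to 1.24 ± 0.53, neither then passing. With the term neither list of the control-fed males passed: the acute phase median went from -0.471 to -0.129 and the male-biased median from -0.509 to -0.313 (adjusted p = 0.304 for each). Of the 70 called genes named by the rule 8 passed with the term: Ces2a, Cyp2c55, Cyp3a25, Dhrs9, Dhtkd1, Igsf23, Pttg1 and Sae1. For 3151 genes (37.4%, chance 2.86%) the groups did not overlap.

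EtOH-fed KO and WT males differed in 3423 genes, 1977 higher and 1446 lower. This balance was 630 and 1235 with the dimmest 33.33% of genes left out, and 3305 and 572 with centred arrays. Of the 3423 genes, 210 differed at least 1.5 fold, and 1784 were not predicted or unnamed loci. Cyp2b9 differed by -5.90 ± 1.02 (SE, n = 4 per group), Cyp2b13 by -4.43 ± 0.68, Cyp2b10 by -3.82 ± 0.82 and Cyp2b23 by -1.30 ± 0.23. Cyp2c55 rose by 1.94 ± 0.31, Sae1 by 1.25 ± 0.08, Igsf23 by 1.09 ± 0.14, Prxl2b by 1.04 ± 0.10 and Dhtkd1 by 0.99 ± 0.11. The zinc transporter gene Slc39a4 rose by 1.06 ± 0.18. Nnmt, nicotinamide N-methyltransferase, fell by 1.54 ± 0.33, Pttg1 by 1.51 ± 0.09 and Clec7a, a receptor gene of myeloid cells, by 1.39 ± 0.36. Ppara rose by 0.61 ± 0.16, Apoa4 by 0.73 ± 0.13 and Cyp2e1, the ethanol-oxidizing cytochrome, by 0.11 ± 0.04.

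NRF2 targets, antioxidant genes, were lower in EtOH-fed KO than WT males. Of 13 measured 7 fell and 0 rose, and 8 fell adjusted over the list alone. Abcc4 differed by -2.77 ± 0.61, Cbr3 by -2.21 ± 0.47, Nqo1 by -1.18 ± 0.33 and Gstm1 by -0.54 ± 0.18. The list was lower at adjusted p = 0.00192, against adjusted p = 0.623 with an estimated correlation. Of 11 Kupffer markers 8 fell, among them Csf1r (-0.63 ± 0.14), C1qa (-0.45 ± 0.13) and Clec4f (-0.45 ± 0.14), and 9 fell adjusted over the list alone. Their list was lower at adjusted p = 0.00192, against adjusted p = 0.623 with an estimated correlation. Of 6 ER stress genes 3 fell (Trib3, Sesn2 and Atf5, by 0.46 ± 0.13, 0.31 ± 0.10 and 0.49 ± 0.18), and 5 fell adjusted over the list alone. The stress list was lower at adjusted p = 0.0427, against adjusted p = 0.623 with an estimated correlation. Of 20 female-biased genes 5 fell, also adjusted over the list alone, and their list was lower at adjusted p = 0.0427, against adjusted p = 0.623 with an estimated correlation. Besides Cyp2b9 and Cyp2b13, these included Ntrk2 (-0.74 ± 0.19) and Slc16a5 (-0.84 ± 0.24). This call rests on WT EtOH array 1, which has female values: without it the median went from -0.44 to -0.0723 and the list did not pass (adjusted p = 0.367). With quantile normalization neither the female-biased list (0.0921) nor the stress list (0.12) passed.

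With a term for the narrow set 54 genes were called in EtOH-fed males, and with quantile normalization 1937. With the term Cyp2b9 differed by -5.85 ± 1.80 and Cyp2b10 by -3.83 ± 1.45. Their differences hardly moved, and they no longer passed because the SE grew. Here too the term was estimated from control-fed KO females and not within males. Of the 68 called genes named by the rule 8 passed with the term (Amacr, Dhtkd1, Igsf23, Ppp1r14a, Prxl2b, Pttg1, Rrm2 and Sae1), and 35 passed without each array in turn. Cyp2c55 went from 1.94 ± 0.31 to 1.75 ± 0.55, Ppara from 0.61 ± 0.16 to 0.75 ± 0.27, Nqo1 from -1.18 ± 0.33 to -1.55 ± 0.57 and Csf1r from -0.63 ± 0.14 to -0.79 ± 0.25, none then passing. Of the 60 calls of named genes that ended with the term, 29 kept a difference at least as large and 6 kept less than 0.5 of it. There was no overlap for 2331 genes (27.7%, chance 2.86%).

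Across the genotype contrasts, 45 genes were higher and 103 lower in KO in all 4. In 19 genes all 16 KO arrays lay above all 16 WT arrays, and in 48 genes all 16 lay below. The control-fed and EtOH-fed female contrasts shared 109 genes higher (11.5 expected by chance) and 153 lower (18.5 expected), and 0 genes went opposite ways. In males 1219 were higher and 700 lower in both (662 and 320 expected), with 16 opposite. Between the sexes, the control-fed contrasts shared 122 higher (78.4 expected) and 164 lower (52.2 expected) with 0 opposite. The EtOH-fed contrasts shared 97 higher (97.4 expected, no more than chance) and 273 lower (113 expected), with 45 opposite. These pairs share no array, but they are not free of a common source. Every KO male array is of narrow spread and no WT male array is, so both male contrasts carry that difference. The overlap beyond chance in males can therefore come from the spread alone. With a term for the narrow set the male contrasts called 96 genes on control diet and 54 on EtOH. Nnt, a mitochondrial transhydrogenase gene, was at 8.21 ± 0.17 (SD, n = 4) in control-fed WT females and 9.07 ± 0.07 in control-fed KO females, and in males at 8.21 ± 0.15 and 9.13 ± 0.07. It was singled out after its values were seen.

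**Figure D2:**
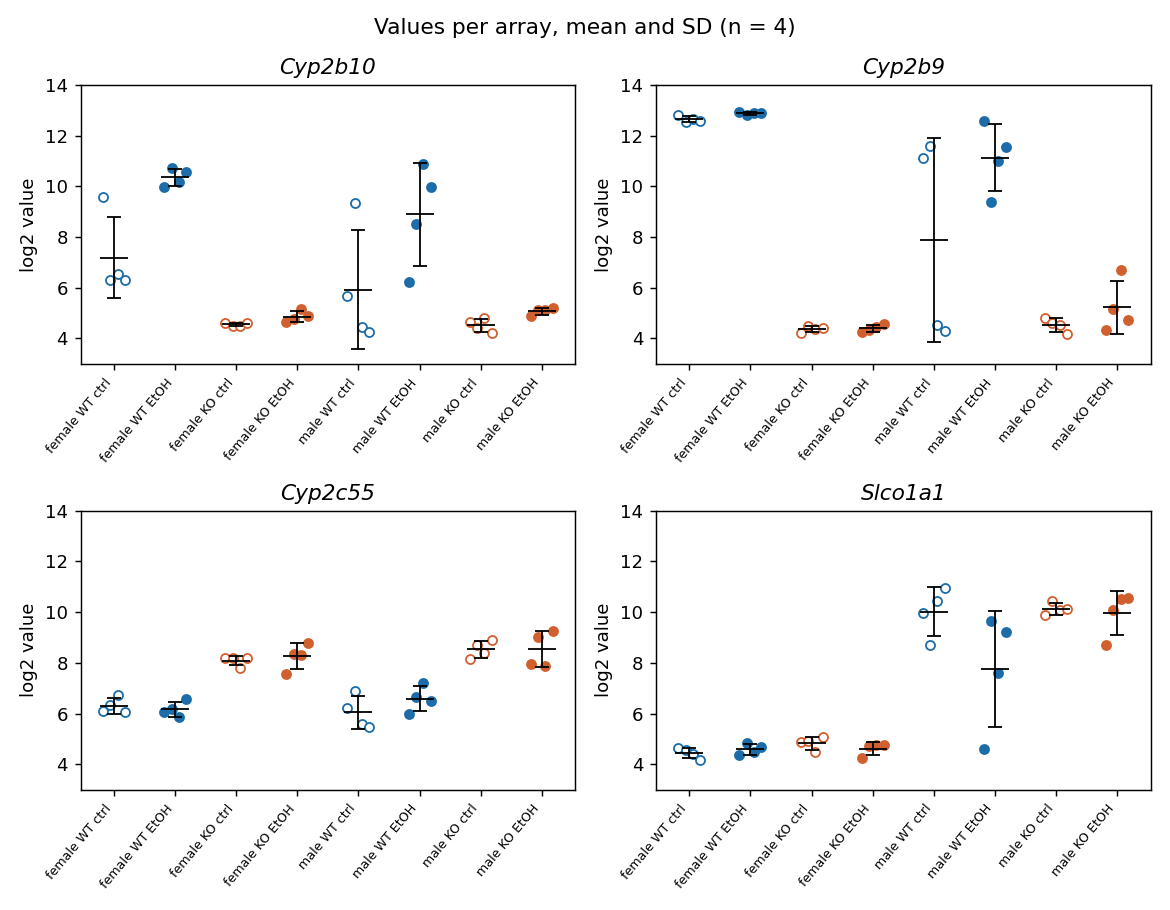
Log2 intensity of Cyp2b10, Cyp2b9, Cyp2c55 and Slco1a1 in each array, by group; points are arrays (open for control diet, filled for EtOH, blue for WT, orange for KO), with the group mean and SD (n = 4). Cyp2b9 lies between 12.53 and 12.93 in WT females and between 4.228 and 4.554 in KO females, and Slco1a1 of 1 EtOH-fed WT male lies at 4.597, among the females.

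The ethanol response of WT females is central to a series whose title concerns female mice. limma called 0 genes, and 941 had an unadjusted p under 0.05 where 421.3 are expected by chance. Cyp2b10 was at 7.19 ± 1.59 (SD, n = 4) on control diet and 10.36 ± 0.34 on EtOH, a difference of 3.17 ± 0.82 (SE) with adjusted p = 0.26. In 3 of the controls it lay between 6.32 and 6.55, and in control array 1 at 9.57. The genes with the smallest p besides a predicted locus were Antxr2 (0.43 ± 0.10), Inpp4a (-0.28 ± 0.07), Acp2 (0.35 ± 0.08) and Sass6 (0.30 ± 0.07), which did not pass (adjusted p = 0.26 for each). Cyp2e1 differed by -0.01 ± 0.04, Ppara by -0.27 ± 0.16, Thrsp by 0.24 ± 0.30 and Cyp3a11 by 0.17 ± 0.11, with none passing. The Cyp2e1 means (13.08 on control diet, 13.07 on EtOH) lay near 13.61, the highest value in the data. Whether changes in transcript still register at that level was not tested.

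In WT females 5 lists passed in the values as deposited, although single genes did not. Of 18 xenobiotic genes 14 had positive differences with a median of 0.307, and 2 rose adjusted over the list alone. That list was higher at adjusted p = 0.00301, against adjusted p = 0.447 with an estimated correlation. Of 13 NRF2 targets 12 were positive (median 0.394), and 0 passed adjusted over the list alone. The NRF2 list was higher at adjusted p = 0.0212, against adjusted p = 0.514 with an estimated correlation. Of 9 one-carbon genes 8 were positive and 2 rose adjusted over the list alone, with the list higher at adjusted p = 0.0212, against adjusted p = 0.447 with an estimated correlation. All 11 Kupffer markers were positive (median 0.254), and 0 passed adjusted over the list alone. They were higher at adjusted p = 0.0212, against adjusted p = 0.514 with an estimated correlation. The 4 sinusoidal endothelium markers, 0 of which passed adjusted over the list alone, were higher at adjusted p = 0.0356, against adjusted p = 0.447 with an estimated correlation. With quantile normalization the xenobiotic list alone of these passed, and the NRF2 (adjusted p = 0.0544), one-carbon (0.153, with the median going from 0.197 to 0.0762), Kupffer (0.0699) and endothelium (0.095) lists did not. Without control array 1, 2 genes were called, without EtOH array 1, 1 gene, and with array quality weights 212. Values did not overlap for 626 genes (7.43%, chance 2.86%).

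In KO females ethanol lowered 2 genes and raised 0. Sult3a2 fell from 8.44 ± 0.56 (SD, n = 4) to 6.12 ± 1.47, by 2.32 ± 0.42 (SE, adjusted p = 0.0279), and the zinc transporter gene Slc39a5 fell by 0.59 ± 0.10 (adjusted p = 0.0234). Next came Gucy2c (-1.14 ± 0.22), Akr1b10 (0.45 ± 0.09) and Pex6 (-0.37 ± 0.08), which did not pass. Cyp2b10 differed by 0.31 ± 0.82, an SE shared with WT groups of far larger spread. Its KO female values did not overlap between the diets (4.492 to 4.62 on control, 4.642 to 5.164 on EtOH). All of them lay below the array medians. Of 5 cytokine genes 3 rose adjusted over the list alone, and of 7 interferon genes 3 did, with 0 called over all genes. Their lists were higher at adjusted p = 0.00638 and 0.0183, against adjusted p = 0.25 and 0.453 with an estimated correlation. The xenobiotic list, with all 18 differences positive, and the Kupffer list, with all 11 positive, were each higher at adjusted p = 0.00638, against adjusted p = 0.453 with an estimated correlation for both. NRF2 targets (adjusted p = 0.0066) and periportal hepatocyte markers (adjusted p = 0.0117) were also higher, against adjusted p = 0.453 and 0.25 with an estimated correlation. Adjusted over the list alone, 0 xenobiotic, 0 NRF2, 0 Kupffer and 2 of 3 periportal genes rose. With quantile normalization the xenobiotic (adjusted p = 0.0991), NRF2 (0.0526) and interferon (0.0537) lists did not pass. Without EtOH array 2, 0 genes were called, without EtOH array 1 or 4, 1 gene each, without EtOH array 3, 39, and without control array 4, 8. The groups did not overlap for 731 genes (8.68%, chance 2.86%).

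In WT males ethanol changed 688 genes, 279 higher and 409 lower. Slc16a5, a monocarboxylate transporter gene, rose by 1.39 ± 0.24 (SE, n = 4 per group, adjusted p = 0.00269), Cyp2a4 by 2.07 ± 0.38, the sulfotransferase gene Sult1a1 by 0.73 ± 0.10 and the kinase gene Mknk2 by 0.69 ± 0.14. Adh4, an alcohol dehydrogenase gene, fell by 0.77 ± 0.15 while Aldh1b1, an aldehyde dehydrogenase gene, rose by 0.63 ± 0.11. Tc2n fell by 0.63 ± 0.11. These genes are among the 8, of 40 called genes named by the rule, that passed without each array in turn. Cyp2b10 rose from 5.93 ± 2.36 (SD, n = 4) to 8.89 ± 2.03 (adjusted p = 0.028), with control array 2 at 9.35 and EtOH array 1 at 6.21. Thrsp rose by 1.33 ± 0.30 and the triglyceride synthesis gene Dgat2 by 0.34 ± 0.08, while Plin2, a lipid droplet coat gene, fell by 0.50 ± 0.16.

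Sex-biased liver genes changed in WT males, to a large part through 1 array. Of 20 female-biased genes all had positive differences, 7 rose, and 12 did adjusted over the list alone (Slc16a5, Cyp2a4, Cyp2b13 by 3.29 ± 0.68 and Fmo2 by 1.29 ± 0.29). Their list was higher at adjusted p = 2e-08, against adjusted p = 0.182 with an estimated correlation. Of 10 male-biased genes 5 fell, and 8 did adjusted over the list alone. Hsd3b5, a steroid dehydrogenase gene, fell by 2.95 ± 0.75, Slco1a1, an organic anion transporter gene, by 2.25 ± 0.62, Elovl3, a fatty acid elongase gene, by 2.07 ± 0.62 and C6 by 1.35 ± 0.35. That list was lower at adjusted p = 3.52e-05, against adjusted p = 0.513 with an estimated correlation. In EtOH array 1 of these males Slco1a1 was at 4.60 and Hao2 at 8.57, in the range of WT females. Without that array the female-biased median went from 0.809 to 0.279 and the male-biased median from -0.805 to -0.546, with adjusted p = 0.000792 and 0.0123. Of single genes, 6 female-biased ones then rose and 2 male-biased ones fell.

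**Figure D3:**
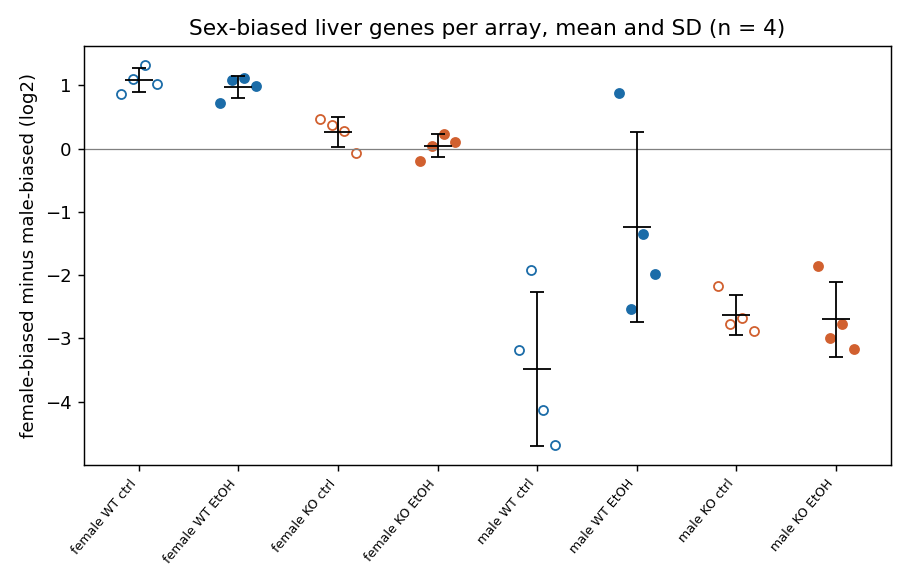
Mean log2 intensity of 20 female-biased genes minus that of 10 male-biased genes in each array, by group; points are arrays (open for control diet, filled for EtOH, blue for WT, orange for KO), with the group mean and SD (n = 4). EtOH array 1 of the WT males lies at 0.886, above the other male arrays, which lie between -4.69 and -1.35.

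Other lists in WT males pointed to xenobiotic and lipid genes. Of 18 xenobiotic genes 3 rose (Ces2a by 0.60 ± 0.15, Abcc3 by 0.70 ± 0.20 and Cyp2b10) and 4 did adjusted over the list alone, with the list higher at adjusted p = 0.000289, against adjusted p = 0.534 with an estimated correlation. All 11 fatty acid oxidation genes had negative differences (median -0.218), of which Hadhb passed (-0.26 ± 0.08), also adjusted over the list alone. The oxidation list was lower at adjusted p = 0.0072, against adjusted p = 0.535 with an estimated correlation. Of 17 genes of fatty acid uptake and lipid droplets 1 rose and 3 fell, and adjusted over the list alone 3 rose and 7 fell (list adjusted p = 0.0514). Of 13 bile acid genes Slc10a1 rose by 0.28 ± 0.08 and Slco1a1 fell, and adjusted over the list alone 2 rose and 4 fell (list adjusted p = 0.424). Abcc4 of the NRF2 list rose by 2.18 ± 0.61, and the list did not pass (adjusted p = 0.0574). Without EtOH array 1 the NRF2 list was higher (adjusted p = 0.000792, median 0.667, 5 genes higher) and the list of uptake and lipid droplets lower (adjusted p = 0.0412), so neither negative result holds without that array. Without it 7 xenobiotic genes rose and 3 fatty acid oxidation genes fell, and both lists still passed.

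The number of genes called in WT males rested on single arrays. It was 47 without EtOH array 3, 275 without EtOH array 4, 1143 without EtOH array 1, 71 without control array 3 and 304 without control array 4. A fit on the 8 arrays alone called 1 gene, and array quality weights gave 1207. The groups did not overlap for 823 genes (9.77%, chance 2.86%).

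In KO males ethanol raised 9 genes and lowered 14, and 4 of these 23 have gene names. The balance turned to 32 higher and 22 lower with quantile normalization, and to 2 and 0 with the dimmest genes left out. A fit on the arrays of this contrast alone gave 1 higher and 0 lower. More genes were still lower with centred arrays (6 higher and 14 lower) and with array quality weights (4 and 15). The zinc transporter gene Slc39a4 rose by 1.03 ± 0.18 (SE, n = 4 per group, adjusted p = 0.0268) and Antxr2 by 0.44 ± 0.10, while Cd209e fell by 0.34 ± 0.08 and Ermn by 0.29 ± 0.06. Cyp2b10 differed by 0.55 ± 0.82 and Thrsp by -0.02 ± 0.30. The SE of Cyp2b10 is shared with the WT groups, whose SD reached 2.36. In KO males its values did not overlap between the diets (4.207 to 4.794 on control, 4.881 to 5.196 on EtOH). All of them lay below the array medians. Of 11 Kupffer markers 10 had negative differences (median -0.262), and 0 passed adjusted over the list alone. Their list was lower at adjusted p = 0.0439, against adjusted p = 0.787 with an estimated correlation and 0.055 with a term for the narrow arrays. Without control arrays 1, 2 or 4 there were 44, 0 and 11 called genes, and without EtOH arrays 1, 2, 3 or 4 there were 35, 11, 2 and 12. The groups did not overlap for 490 genes (5.82%, chance 2.86%).

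Diet effects of different groups were set beside each other. Calls were few, with 0 genes in WT females, 2 in KO females, 688 in WT males and 23 in KO males. Between genotypes and between sexes 0 genes were called in the same direction in a pair of diet contrasts. By chance at most 0.298 higher and 0.68 lower were expected in a pair, so the count of 0 does not tell whether responses are shared. Across genes, which are not independent replicates, the log2 differences had a Pearson r of 0.386 between WT and KO females and 0.0971 between WT and KO males. Between females and males it was 0.346 in WT and 0.22 in KO.

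The interaction terms asked whether the ethanol response itself differed. For diet by genotype limma called 0 genes in females and 0 in males, with 719 and 1523 genes at an unadjusted p under 0.05. For Cyp2b10 the response differed between KO and WT by -2.86 ± 1.16 (SE, n = 4 per group) in females and -2.41 ± 1.16 in males (adjusted p = 0.563 and 0.271). For Thrsp in males it differed by -1.35 ± 0.43 (adjusted p = 0.125), and for the ceramide synthase gene Cers6 and for Slc39a4 in males by -0.81 ± 0.16 and 1.26 ± 0.26 (adjusted p = 0.0667 for each). In females Tmem106c (-0.31 ± 0.07) and Zfp36l2 (-0.51 ± 0.13) were among those with the smallest p, and none passed. The male count became 42 and 97 without control arrays 1 and 2 of WT, 167 without EtOH array 1 and 3 without EtOH array 2. It was 2 without WT control array 4, 5 and 12 without KO control arrays 1 and 2, and 2 without KO EtOH array 3.

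Some lists differed in their response between male genotypes. The differences of all 10 male-biased genes were positive (KO minus WT) and 19 of 20 female-biased genes were negative, and both lists passed at adjusted p = 1.07e-05, against adjusted p = 0.392 with an estimated correlation. Adjusted over the list alone 8 male-biased genes passed upwards and 8 female-biased genes downwards. Without WT EtOH array 1 the female-biased median went from -1.05 to -0.444 (adjusted p = 0.00604) and the male-biased median from 1.02 to 0.757 (adjusted p = 0.00527), and the NRF2 list then passed downwards (adjusted p = 0.00626). The xenobiotic list (17 of 18 negative) and the Kupffer list (all 11 negative) were lower at adjusted p = 0.0376 and 0.00107, and the acute phase list (10 of 13 positive) was higher at adjusted p = 0.0252, against adjusted p = 0.61 with an estimated correlation for each of the 3. Of the xenobiotic, Kupffer and acute phase genes 0 passed adjusted over the list alone, and the acute phase list did not pass with quantile normalization (0.0821). In females 0 of 24 lists passed.

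For diet by sex limma called 0 genes in WT and 0 in KO (1155 and 851 at an unadjusted p under 0.05), and 0 for the term of diet, genotype and sex together (685). In WT, Dhrs9 responded differently in females and males by 1.33 ± 0.29 and Edem3 by 0.45 ± 0.10 (adjusted p = 0.182 for each), and in KO Icos by 0.75 ± 0.17 (adjusted p = 0.256). The WT female-biased and male-biased lists passed at adjusted p = 2.12e-07 and 4.4e-05, against adjusted p = 0.28 and 0.536 with an estimated correlation, and adjusted over the list alone 1 and 5 of their genes passed. Without male EtOH array 1 their medians went from -0.84 to -0.497 and from 0.919 to 0.545 (adjusted p = 0.000946 and 0.00551). Fatty acid oxidation genes, 10 of 11 with positive differences (female minus male), passed at adjusted p = 0.0125, against adjusted p = 0.568 with an estimated correlation, and 3 passed adjusted over the list alone. With quantile normalization that list did not pass (0.0607). In KO the Kupffer list, all 11 positive with 0 passing adjusted over the list alone, was higher in females at adjusted p = 4e-06, against adjusted p = 0.522 with an estimated correlation. In WT the count was 1, 2 and 1 without male control arrays 1, 2 and 4, and in KO 2 and 1 without male EtOH arrays 1 and 3. The joint term called 1 gene without male WT control array 1 or 2, male KO EtOH array 2 or female KO control array 4.

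Control-fed WT females and males were compared as a check of sex labels. Of 395 called genes 149 were higher in females and 246 lower. Cyp2b13 was higher in females by 5.68 ± 0.68 (SE, n = 4 per group), Hao2, a hydroxyacid oxidase gene, by 4.66 ± 0.61 and Cyp17a1 by 3.10 ± 0.48, while Slco1a1 differed by -5.57 ± 0.62 and Elovl3 by -4.63 ± 0.62. Of 20 female-biased genes 17 were higher (18 adjusted over the list alone) and of 10 male-biased genes all 10 were lower, also adjusted over the list alone. Both lists passed (adjusted p = 9.08e-30 and 8.82e-20), and these were the 2 calls of 56 that held with an estimated correlation (0.000264 and 0.00299 as adjusted p). The xenobiotic list was higher in females at adjusted p = 0.049, against adjusted p = 0.573 with an estimated correlation and 0.0566 with a term for the narrow arrays. Of its 18 genes 4 were higher, and 5 adjusted over the list alone, with Cyp3a16 at 2.79 ± 0.41 and Cyp3a44 at 1.24 ± 0.21. Of 5 pericentral hepatocyte markers 0 passed (list adjusted p = 0.737). Without male control array 3 the count was 206 and without female control array 1 it was 255. The groups did not overlap for 922 genes (10.9%, chance 2.86%).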

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

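The tests of loss of PXR alone and of a term for the narrow arrays were chosen after the result was seen. So were the list tests that left out an EtOH-fed WT male array, and the genes checked for single arrays beyond the fixed set. The interaction tests and the other divisions of the arrays were planned before the data were examined. For the remaining tests of explanations the prediction was written before its result, but the patterns and arrays they concern were picked from the data.

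Single arrays lay far from the other 3 of their group in 16 of 168 groups checked, where chance gives about 1 in 20. An array counted as far when Dixon's ratio, its gap to the nearest array over the range of the group, passed the 5% level for 4 values. In 20000 simulated normal groups of 4 this marked 5.07%. Part of the genes were chosen after their values were seen, so the count of 16 does not test whether odd arrays exceed chance. For Nr1i2 these were control array 2 of the WT males (8.8) and EtOH array 4 of the KO females (8.83). For Cyp2b10 it was control array 1 of the WT females (9.57), for Thrsp control array 4 of the KO males (11), for Slco1a1 EtOH array 1 of the KO females (4.24) and for Hao2 EtOH array 1 of the WT males (8.57). Cyp2e1 stood apart in WT male control array 4 (13.16), WT male EtOH array 1 (13.15) and KO male EtOH array 3 (13.25). Sult3a2 did in WT female control array 3 (4.68) and KO male control array 1 (3.18), Cyp2c55 in KO female control array 3 (7.81) and Nnt in KO male control array 2 (9.02). Of the list means, female-biased genes stood apart in KO female EtOH array 1 (7.88), male-biased genes in KO male EtOH array 1 (8.94) and Kupffer markers in WT female control array 4 (8.73).

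The ethanol response differed between groups by an interaction test in 19 pairs of a list and a contrast, which cover 9 different lists. With a correlation estimated per list, camera called 0 of the 19, and fry called 0 lists in each interaction. Between male genotypes these were xenobiotic genes (adjusted p = 0.0376), the acute phase (0.0252), male-biased and female-biased genes (1.07e-05 each) and Kupffer markers (0.00107). Between the sexes in WT they were fatty acid oxidation (0.0125), male-biased genes (4.4e-05) and female-biased genes (2.12e-07). Between the sexes in KO they were cytokines (0.0124), the acute phase (0.046), the interferon response (0.046), Kupffer markers (4e-06) and T and NK cell markers (0.0124). Of these, the acute phase did not pass with centred arrays (0.0722), the interferon response with quantile normalization (0.0852) or a term for the narrow arrays (0.0854), and the T and NK markers with that term (0.0857). For diet, genotype and sex together they were the acute phase (0.00177), male-biased genes (0.00121), female-biased genes (0.000205), the interferon response (0.0179), Kupffer markers (0.000523) and T and NK cell markers (0.00231). Without WT male EtOH array 1 the male-biased median of this joint term went from -0.961 to -0.625 (adjusted p = 0.0174), and the xenobiotic (0.0104) and NRF2 (0.00278) lists passed as well.

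Probes without a listed gene also passed the threshold. There were 2 for the diet effect in KO females, 81 in WT males and 6 in KO males. For the genotype effect there were 75 in control-fed females, 1156 in control-fed males, 138 in EtOH-fed females and 815 in EtOH-fed males, and for sex 47.

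The first pattern is the set of 10 arrays of narrow spread, which holds all 8 KO male arrays. Loss of PXR alone is argued against, since 6 KO female arrays lay outside the set, 2 of them in a group with 2 arrays inside. A compression of each array's scale would be removed by quantile normalization, which left 2502 calls in control-fed males (1834 to 2380 without each array in turn). This is more than a bound of 762 for compression as the whole cause. The bound was set from the 508 calls in control-fed females with quantile normalization. A larger genotype effect in males would also leave more calls, so the count cannot tell whether compression is the whole cause. The share of calls left, 0.485 to 0.549 of the fits without the same array, leaves open whether it is a part of the cause. A batch that the labels do not give cannot be told apart from genotype in males, because the set and genotype go together in every male array. A term for the set, estimated from control-fed KO females alone, raised the median SE 1.7 times. It reduced the median size of differences to 0.736 of its value. Sex and genotype together stay open as a biological source and were not tested.

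The second pattern is the Cyp2b10 level of single WT arrays. Female control array 1 lay at 0.695 on the diet axis of the other 7 arrays, where -1 is the control mean and 1 the EtOH mean. This is on the EtOH side, as a wrong diet label would require. Placed in turn on axes drawn without them, the EtOH arrays lay at -0.0162 to 0.684 and the other controls at -0.876 to -0.631. Those axes counted array 1 as a control, so these positions are not on the same scale as its own. Male control array 2 lay at 0.484 on the axis of the remaining 6 arrays and EtOH array 1 at -0.396, as an exchange of these 2 would require. An exchange between males leaves the female values of EtOH array 1 unaccounted for. An uneven intake of ethanol could give the position of EtOH array 1 and was not tested. It could not give those of the control arrays if their labels are right, since the control diet is not the EtOH diet.

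The third pattern is EtOH array 1 of the WT males. It lay on the female side for 20 of 21 genes that part the other 15 males from all 16 females, where no other male had more than 4. If ethanol had moved a male liver towards the female pattern, the array was predicted to lie on the EtOH side of the diet axis of the WT females. It lay at -1.26, among the male WT controls (-1.44 to -0.286) and below the other EtOH-fed WT males (-0.00361 to 0.78). EtOH-fed KO males lay at -1.36 to -0.397, so EtOH arrays can lie on the control side. The axis also rests on a contrast with 0 called genes and counts female control array 1 as a control. The position therefore does not settle whether ethanol moved this liver. An array of a female liver under a male label stays open, as only 1 gene on the sex chromosomes (Alas2, at 7.41, or 100 percent of 1 gene) parts the sexes. A female liver from the control diet is a candidate explanation that its Cyp2b10 of 6.21, below the 6.32 to 6.55 of 3 WT female controls, does not settle.

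Other divisions of the same arrays were fitted to see whether chance can be excluded. For genotype the real division alone among 35 gave so many genes: 470 in control-fed females (highest other 2), 4684 in control-fed males (303), 1076 in EtOH-fed females (7) and 3423 in EtOH-fed males (370). The same held for 23 genes in the diet effect in KO males (1 of 35, highest other 15) and 395 for sex (1 of 35, highest other 80). A share of 1 in 35 is the smallest this check can give and was not adjusted for the number of contrasts. It therefore does not exclude chance. The 23 genes of KO males became 0 without control array 2 and 1 in a fit on their arrays alone. For 2 genes in KO females (2 of 35, highest other 3) and 688 in WT males (2 of 35, highest other 897) another division gave more. The division with 897 exchanges control array 2 with EtOH array 1. For the diet effect in WT females and the interactions limma called 0 genes, with 941, 719, 1523, 1155, 851 and 685 at an unadjusted p under 0.05. A count of 0 is reached by every division (35 of 35, and 100 of 100 draws for each interaction) by construction, so these say nothing about chance. The highest others were 1 for the diet effect in WT females, 1 and 69 for diet by genotype in females and males, 20 and 2 for diet by sex in WT and KO, and 2 for the joint term. The draws with 69 and 20 point to a structure among these arrays.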

How the results depend on the processing

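The term for the 10 narrow arrays, the omission of 2 narrow arrays and the list tests without EtOH array 1 of the WT males were chosen after the data were seen. Of 343 named gene results, 100 kept direction and side of the threshold in all alternatives run; over all alternatives 5535 values kept both, 888 no longer passed, 73 newly passed and 7 reversed. The cause was not tested unless given.

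Counts moved over 1.5 times as follows. With all probes: diet effect in KO females 5 (from 2), diet by genotype in males 4 (from 0). With the dimmest 33.33% left out, and so fewer genes tested: KO females 4, diet effect in KO males 2 (from 23), genotype in control-fed males 2583 (from 4684) and EtOH-fed males 1865 (from 3423). With centred arrays: KO females 76, shared diet calls 1 (from 0). With quantile normalization: KO females 15, KO males 54, control-fed males 2502, EtOH-fed males 1937, diet by genotype in males 20, shared diet calls 1. With trend and robust moderation: KO females 1. With array weights: WT females 212 (from 0), KO females 5, WT males 1207 (from 688), control-fed females 769 (from 470), diet by genotype in males 28, sex 626 (from 395), shared diet calls 79. With only a contrast's arrays, and so fewer samples: KO females 10, WT males 1, KO males 1, control-fed males 3061, EtOH-fed males 1838, diet by genotype in males 2, sex 133, shared diet calls 1. With the replicate block: KO females 0. With the term for the narrow set: KO females 5, control-fed females 269, control-fed males 96, EtOH-fed males 54, diet by genotype in males 16, the joint term 1, shared diet calls 1. Without the 2 narrow arrays: KO females 4, control-fed females 271. Of 336 list tests camera called 56. With an estimated correlation it called 2, and camera without EtOH array 1 of the WT males called 61. The calls of fry numbered 32, with 0 in each interaction and 0 in the diet effects of WT females, KO females and KO males. Of the 56, 51 still passed with centred arrays, 42 with quantile normalization and 49 with the term for the narrow set.

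Centring changed the split of higher and lower genes, to 400 and 145 in control-fed females, 3685 and 952 in control-fed males and 3305 and 572 in EtOH-fed males.

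With 1 array left out in turn, the diet counts ranged from 0 (without control array 2) to 2 (without control array 1) in WT females, 0 (EtOH array 2) to 39 (EtOH array 3) in KO females, 47 (EtOH array 3) to 1143 (EtOH array 1) in WT males and 0 (control array 2) to 44 (control array 1) in KO males. Genotype counts ranged from 289 to 419 in control-fed females (lowest without WT array 1), 3784 to 4457 in control-fed males, 502 to 1152 in EtOH-fed females (lowest without KO array 1) and 2385 to 3361 in EtOH-fed males. Diet by genotype gave 0 in females and 0 to 167 in males (highest without WT EtOH array 1), diet by sex 0 to 2 in WT (highest without male control array 2) and 0 to 2 in KO (highest without male EtOH array 1), and the joint term 0 to 1 (highest without WT male control array 1). Sex gave 206 (without male control array 3) to 467.

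The difference of Nr1i2 in EtOH-fed males, which did not pass (-0.033), reversed to 0.054 with centred arrays, 0.04 with quantile normalization, 0.018 without WT EtOH array 2, 0.04 without KO EtOH array 2 and 0.046 without KO EtOH array 4, and ranged from -0.132 to 0.054. That of Cr2 in control-fed males reversed to -0.033 with quantile normalization and -0.005 with the term for the narrow set.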

Other observations

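The tests of DNA beside Nr1i2 and around Cyp2b10 were chosen after the result was seen. For the others in this part the prediction was written before its result.

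In 67 genes all 16 KO arrays lay on one side of all 16 WT arrays. A hypothesis is that some of these differ because the KO line carries DNA of another strain. A first count of neighbouring pairs away from chromosome 16 gave 4 pairs against 1.79 on average in 10000 random draws (permutation p = 0.107), which leaves it open. Beside Nr1i2, 1 separating gene (Slc35a5) lay among the 20 genes on either side, as many as in 18% of 7309 windows elsewhere, which also decides nothing. After these results a further test, with a wider window and named genes alone, counted 5 (Ccdc61, Clptm1, Igsf23, Zfp235 and Sirt2) among the 50 genes on either side of Cyp2b10 on chromosome 7, where 0.651% of 2613 windows elsewhere had as many. The fullest windows held 7, all 3 of them on chromosome 7 and 2 of them with Cyp2b10 inside (permutation p = 0.00799 in 1000 draws, whose fullest window held 4 at the median and up to 7). Windows on other chromosomes reached 5. A donor segment around the Cyp2b genes may contribute to the low Cyp2b9 and Cyp2b13 of the KO females, but the values do not show that a segment causes it. In 2 control-fed WT male arrays both were as low. Both genes are on the female-biased list, so low values in males do not weigh for or against a segment. A further reserve is that the window test around Cyp2b10 is the third test of this kind and that its window and genes were chosen after the first 2.

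A further hypothesis was that ethanol moves male livers towards the female pattern of sex-biased genes. In WT males 87.9% of 33 sex-differing genes moved that way, and without EtOH array 1 it was 75.8%. Of 35 divisions of the arrays 9 gave as high a share (highest 100), the real one included. The other divisions counted in either direction and the real one in the female direction alone, which made it harder to stand out. The share is thus not shown to exceed chance. In KO males 41.9% of 62 genes moved that way (35.5 to 50% without each array in turn), so no such move was seen there. Other divisions, scored in either direction, reached 72.6%, so the share varied widely and does not exclude a move.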
